A study of Danio rerio with 12 samples.

How the data were processed

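The study measured transcripts in the pineal gland, the melatonin-producing, light-sensitive gland on top of the zebrafish brain, with a 1-colour Affymetrix zebrafish expression array. Per the labels, the fish were adults of both sexes of a transgenic line in which the regulatory regions of aanat2, the gene of the rate-limiting enzyme of the melatonin rhythm, drive a green fluorescent protein, which let the gland be seen during dissection. Each of the 12 arrays held RNA from a pool of 12 glands. The fish were held in darkness from the evening before sampling. At 6 circadian times (CT2, CT6, CT10, CT14, CT18 and CT22), counted in hours from subjective dawn, 1 pool came from fish kept in the dark and 1 pool from fish given 1 h of light at 12 W/m2 just before sampling. Per the labels' protocols, RNA was extracted on silica columns and amplified linearly in 2 rounds from an oligo(dT) primer before biotin labelling, so signals come mainly from the 3' ends of transcripts.

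The deposited values are intensities, 1 linear MAS5 signal per probe set and array, per the submitters' processing notes, which name GCOS and MAS5 without versions. In the deposited table the mean signal after removal of the lowest and highest 2% of probe sets was 200.035 to 200.042 on every array, so the authors had scaled the arrays to a common trimmed mean. No further scaling was applied. The table had 15617 rows, of which 115 were Affymetrix control probe sets and 15502 were not. The platform annotation gave 1 gene symbol for 10795 probe sets, several for 135 and none for 4572; of those with 1 symbol, 10711 had an Entrez ID in the current gene table and 1 symbol was updated. Genes are named only from probe sets with 1 symbol. No chromosome positions are given, since no source used here names a genome build for the array. The number of arrays, with 1 per time and treatment, limits the precision.

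A value of 13, the 10th percentile of all signals, was added before taking log2, so a fold change of a weak probe set is understated. Probe sets were kept when their mean log2 value over the 12 arrays was at or above the 40th percentile of the non-control probe sets, 6.16, which is a signal of 58.3. This kept 9301 probe sets for 6025 genes. Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and an adjusted p threshold of 0.05. A probe set past that threshold is said to be called. For light against dark, the time point was a 6-level block, because each light pool had a dark pool of the same circadian time; the 6 time points act as the replicates, with 5 residual degrees of freedom, and p-values measure the spread of the light difference over times and pools. Each light difference is given as the mean of the 6 within-time differences ± SE. This pairing comes from the labels' time points. The deviations of the light and dark arrays of 1 time correlated across genes with r between -0.05 and 0.30. For arrays of different times r lay between -0.37 and 0.37, so these values do not bear the pairing out by themselves. For time of day, an F-test of a cosine and a sine of 24 h period was made beside the light term, with 8 residual degrees of freedom. For a light response that varies over the cycle, the products of light with the cosine and sine were tested jointly, and, for subjective day (CT2, CT6, CT10) against subjective night (CT14, CT18, CT22), the product of light with night.

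For tests of gene lists and for named genes, 1 probe set stood for a gene, that with the highest mean log2 value. Of 27 lists of clock, photoreceptor, melatonin, stress, metabolic and housekeeping genes and of markers of other tissues, fixed before the data were examined, those with at least 5 kept genes were tested. Camera with a preset correlation of 0.01 was used for light, with an estimated correlation and fry as alternatives, and Fisher's exact test for time of day. Named were per2, cry1a, cry5, aanat2 and exorh in every case; up to 12 genes up and 12 down with the largest log2 difference among called genes with the same sign at all 6 times; the list members called over all genes or over the list alone, or else the 3 with the smallest p; and, for time of day, the 15 largest amplitudes and the called members of the clock and melatonin lists. Asmt, also on that list of fixed names, had no kept probe set under that name.

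The steps were tested on simulated data with 200 of 9301 probe sets changed. For light against dark, 69.5% of changes of 1 log2 unit and 98.5% of changes of 2 were recovered, with 9 and 5 false calls. For time of day, 90% and 99.5% of cosine amplitudes of 1 and 2 were recovered, with 10 and 11 false calls. For the light response by time, 7.5% and 86% were recovered, and for subjective day against night 0% and 58% for changes of 1 and 2 log2 units, so changes of 1 unit were mostly out of reach. In the simulation of gene lists, 5 of 5 shifted lists and 0 of 20 unshifted ones were called. The simulated probe sets were independent of each other, so this does not cover false calls of lists whose genes are correlated. In the data the estimated correlation was 0.16 for the clock negative limb, 0.27 for skeletal muscle and 0.47 for skin. No offset shared by a group of arrays was simulated. The counts of false calls therefore do not cover an offset that coincides with light.

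Alternatives were other added values (1 and 43), no filter or a filter at the 60th percentile, quantile or cyclic loess normalization, eBayes without the trend or with robust estimation, a threshold of 0.1, leaving out both arrays of each time point in turn, other models without the block, array weights, an exact sign-flip test, 1 probe set per gene, and time of day from the dark or light arrays alone or as a 6-level factor. After the control probe sets had been seen, models with the spike-in class or level of the arrays were added. Figures were drawn with matplotlib 3.10.9.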

Results

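The data comprised 12 arrays of zebrafish pineal glands, 6 from fish kept in constant darkness and 6 from fish given 1 h of light, with 1 array of each kind at CT2, CT6, CT10, CT14, CT18 and CT22. The median deposited signal was 70.31 on the lowest and 99.5 on the highest array, and Pearson's r between arrays over the kept probe sets lay between 0.870 and 0.959. The comparisons asked which transcripts differed after light, which varied with circadian time, and whether the response to light varied with circadian time.

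The bacterial and phage transcripts that are spiked into the hybridisation mix (bioB, bioC, bioD and cre) divided the arrays into 2 classes. Their mean log2 signal over 18 probe sets was 9.53 to 9.78 on the dark arrays of CT2, CT6, CT10, CT14 and CT18. It was 10.27 to 11.18 on the dark array of CT22 and on all 6 light arrays, a 1.93-fold difference of the class means. The gap between the classes was 0.48 log2. A larger gap of 0.54 lay within the higher class, between the light arrays of CT18 (10.65) and CT14 (11.18). The GAPDH control probe set at the 3' end also followed these classes, with a mean log2 signal of 12.65 on the 5 dark arrays and 11.92 on the other 7. No label names a batch. Only at CT22 did the light and the dark array lie in the same class, so the differences at that time are given below for the called genes named for light. The 2 pools of CT22 differed in markers of other tissues, which limits this check. Brain neuron markers lay at 0.56 log2 in the light pool and -0.25 in the dark pool, as mean deviations from their means over the 12 arrays. Oligodendrocyte markers lay at 0.64 and -0.34.

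**Figure D1:**
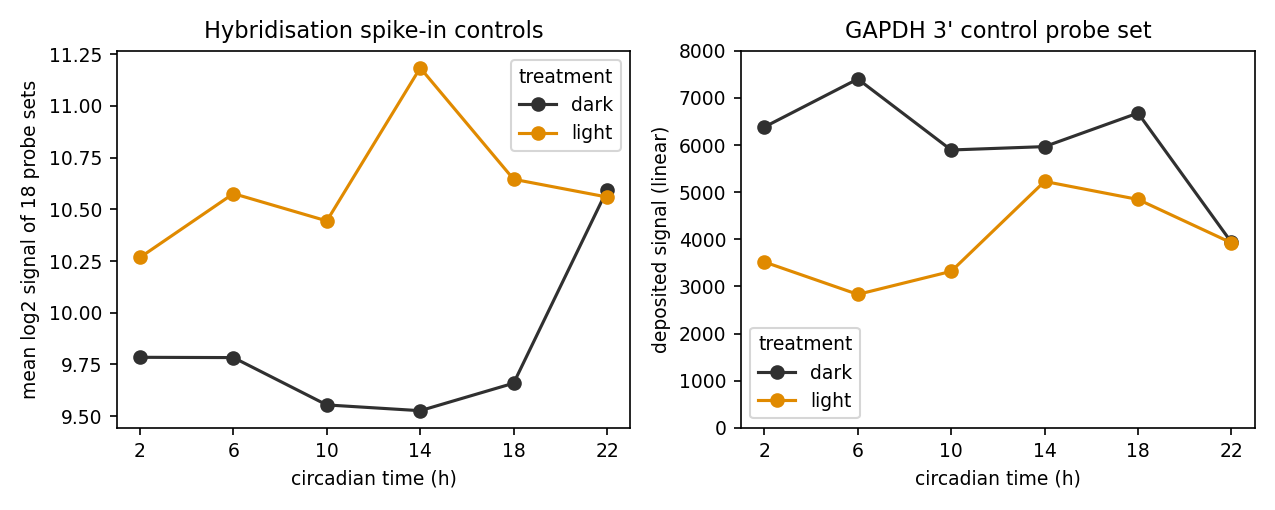
Mean log2 signal of 18 spike-in control probe sets (left) and deposited linear signal of the GAPDH 3' control probe set (right) against circadian time in hours, 1 point per array, dark in black and light in orange. The dark spike-in values were 9.53 to 9.78 from CT2 to CT18 and 10.59 at CT22, where the dark array lay among the light arrays.

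Light for 1 h was followed by higher levels of the clock genes per2 and bhlhe40 and of 4 of 46 early-response genes, while 3 others of these were lower. Per2, the clock repressor gene best known for its induction by light, was 3.08-fold higher in light (1.62 ± 0.20 log2, SE, n = 6 pairs, adjusted p = 0.00183 by limma) and higher at all 6 times. The transcription factor genes jun (3.38-fold) and klf9 (3.31-fold) rose as well, as did pfkfb4b (4.50-fold), whose enzyme is a regulator of glycolysis. Dusp1, a phosphatase that inactivates MAP kinases, was 3.75-fold lower, and sik1, a kinase gene induced by cAMP in many tissues, was 3.72-fold lower. In all, 147 probe sets rose and 68 fell, by 1.48-fold to 4.50-fold (median 1.87); 67 and 46 of these had 1 gene symbol.

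Among the 12 largest rises, pfkfb4b changed by 2.17 ± 0.19 log2 (adjusted p = 2.84e-04 by limma), LOC567909 by 2.00 ± 0.18, jun by 1.76 ± 0.16 and klf9 by 1.73 ± 0.20. The uncharacterised genes wu:fe14d05, si:rp71-1c10.7 and si:ch211-195b15.8 rose by 1.62, 1.33 and 1.28. Fkbp5, an immunophilin that binds steroid receptor complexes, rose by 1.33 ± 0.19, nfil3-6, a bZIP repressor, by 1.32 ± 0.15, acta1a, a skeletal muscle actin, 2.46-fold, and osbpl7, of the oxysterol-binding family, by 1.29 ± 0.25. At CT22, where both arrays were of 1 spike-in class, the differences of LOC567909 (2.13), pfkfb4b (1.73), per2 (1.66), jun (1.58), klf9 (1.47), si:rp71-1c10.7 (1.38) and nfil3-6 (0.93) kept their direction and most of their size. Those of si:ch211-195b15.8 (0.78), acta1a (0.72), fkbp5 (0.68), wu:fe14d05 (0.44) and osbpl7 (0.20) were smaller than their means by over 1.5 times.

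Among the 12 largest falls, dusp1 changed by -1.91 ± 0.23 log2 and sik1 by -1.90 ± 0.23 (adjusted p = 0.00183 for each by limma), and at CT22 the values were -2.11 and -2.39. The chemokine scavenger receptor ackr3b fell by 1.24 ± 0.23, zgc:193593 by 1.27, fosab, the c-Fos gene, by 1.22 ± 0.28 and ggctb, of glutathione turnover, by 1.21. Another kept probe set of fosab gave -0.54, and fosab was no longer called without the time-point block (adjusted p = 0.337 by limma). The other falls were gtf2f2a (-0.96), rnaseka (-0.95), the Notch target hey1 (-0.94), the carnitine carrier slc25a20 (-0.90), the E2F partner tfdp1b (-0.88) and ccng2 (-0.84). At CT22 the differences of ackr3b (-0.73), ggctb (-0.61), hey1 (-0.50) and slc25a20 (-0.18) were smaller than their means by over 1.5 times, those of rnaseka (-0.67) and ccng2 (-0.60) by less, and those of fosab (-2.71), zgc:193593 (-1.38), gtf2f2a (-1.32) and tfdp1b (-0.96) were larger than their means.

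**Figure D2:**
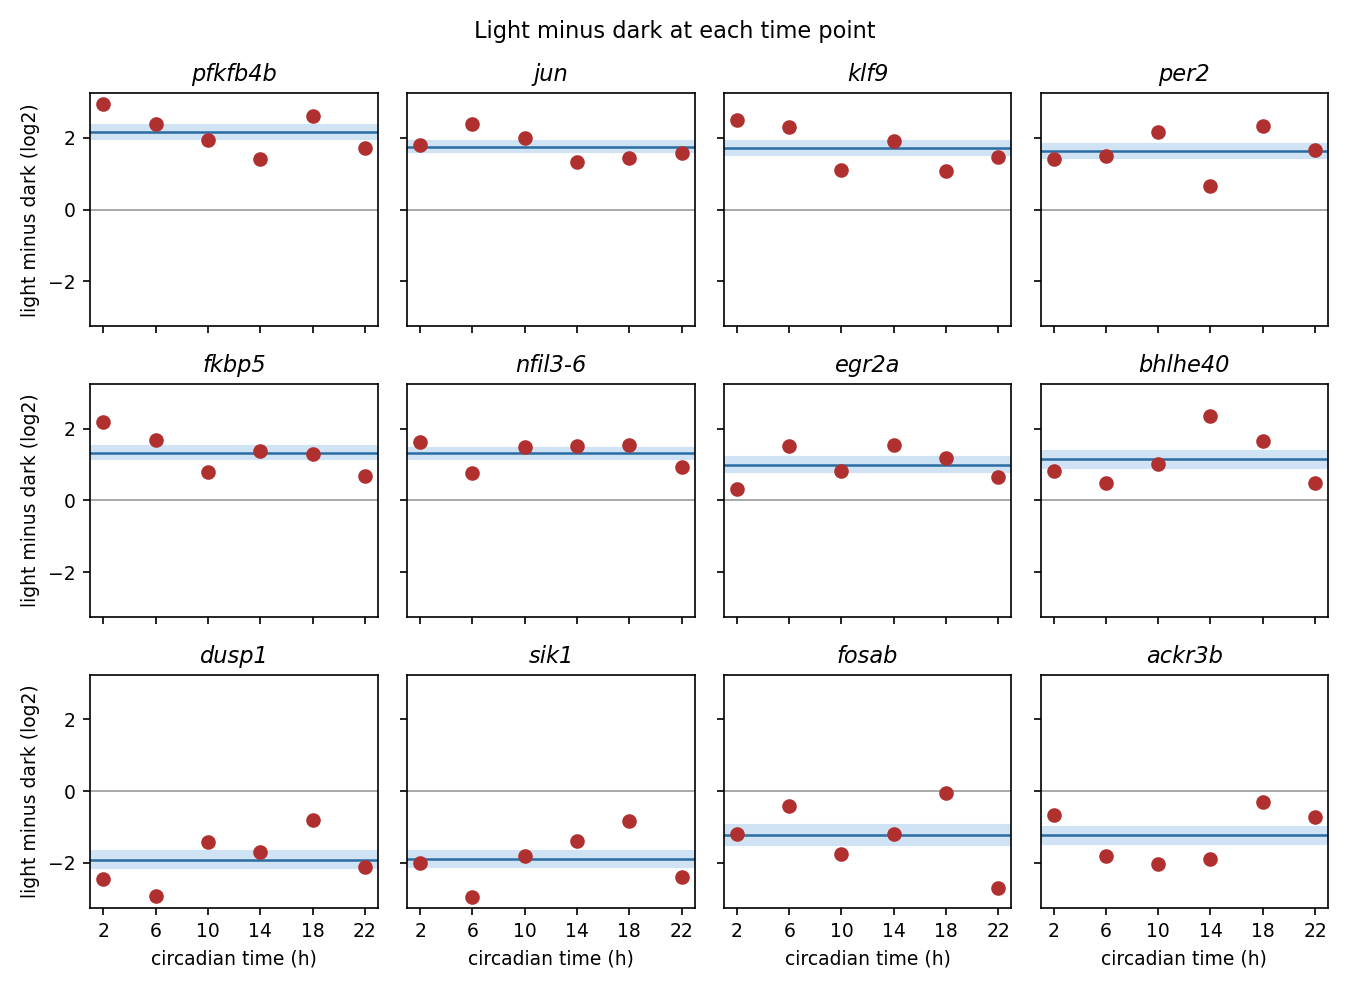
Light minus dark difference (log2, vertical axis) against circadian time in hours for 12 genes called in light versus dark, 1 point per time point, with the mean as a line and ± 1 SE as a band. All points of pfkfb4b, jun, klf9, per2, fkbp5, nfil3-6, egr2a and bhlhe40 lie above 0, and all those of dusp1, sik1, fosab and ackr3b below 0, with the fosab value at CT18 at -0.05.

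The clock negative limb, the genes of the repressors that feed back on the clock, was higher in light as a list. All 10 kept genes had a positive difference (median 0.38 log2), 2 were called, per2 and bhlhe40 (1.14 ± 0.22), and 4 were called when adjusted over the list alone, with ciarta (0.94) and cry1a (0.50) added; at CT22 bhlhe40 differed by 0.49, ciarta by 0.44 and cry1a by 0.83. The list passed camera at the preset correlation (adjusted p = 6.90e-04) but not with an estimated correlation (adjusted p = 0.668 with an estimated correlation) or by fry (adjusted p = 0.107), nor without the time-point block (camera adjusted p = 0.0835). With spike-in class in the model its camera adjusted p was 7.50e-04 (adjusted p = 0.821 with an estimated correlation). Of the PAR bZIP and nfil3 factors, nfil3-6 was called and tefa (0.41 ± 0.16, at CT22 0.10) passed over the list alone. None of the 8 clock positive limb genes was called, and clocka, npas2 and bmal1a had the smallest p.

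The 46 kept immediate-early genes split evenly, with 23 positive and 23 negative differences. Over all genes, 4 rose (jun, klf9, fkbp5 and egr2a, the last by 1.00 ± 0.22, at CT22 0.65) and 3 fell (sik1, dusp1 and fosab). Adjusted over the list alone, tob1a (0.48) and klf11a (0.47) were also higher and mcl1a (-0.53), an anti-apoptotic gene, lower, making 6 and 4. Camera gave an adjusted p of 0.833 for the list, whose members went both ways.

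Genes of the pineal's own functions mostly did not pass the threshold. Cry1a differed by 0.50 ± 0.18 (adjusted p = 0.174 by limma), cry5, the (6-4) photolyase gene that repairs ultraviolet damage, by 0.32 ± 0.22 (adjusted p = 0.482), aanat2 by 0.30 ± 0.30 (adjusted p = 0.635) and exorh, the pineal opsin gene, by 0.34 ± 0.25 (adjusted p = 0.495). Aanat2 and exorh were lower in light at CT22, by -0.89 and -0.84, where the light pool was also higher in brain neuron and oligodendrocyte markers. Of the 19 melatonin and pineal identity genes, 14 had a negative difference and tph1a, which encodes the first enzyme from tryptophan to serotonin, was lower over the list alone (-0.55 ± 0.14, adjusted p = 0.0725 over all genes by limma). Of 26 phototransduction genes, 18 were positive and pde6ha, a cone phosphodiesterase subunit, rose by 0.92 ± 0.14 (at CT22 0.74). Opn1lw1, the red cone opsin, was lower over the list of 5 retinal rod and cone genes alone (-0.47 ± 0.12).

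Genes of basic cell functions moved in both directions. Of 73 ribosomal protein genes, 32 were positive and 41 negative; rpl35a (0.70) and rpl31 (0.63) rose, and over the list alone rpl38 and rps21 were also higher and rpl4 and rpl35 lower. At CT22 rpl35a, rpl38 and rps21 differed by -0.07, -0.09 and -0.13, and rpl31 by 0.12. Of 73 respiratory chain genes, 33 were positive and none was called over all genes; over the list alone atp5f1e was higher, and atp5f1c and ndufa9a lower. Of 46 genes matched by the proteasome pattern, psmd6 (-0.62 ± 0.13, at CT22 -0.46) fell, and so did psme3ip1 (-0.69, at CT22 -0.88), whose product is an interactor and not a subunit. Of 32 antioxidant genes, 24 were negative; keap1a, the gene of the sensor that restrains Nrf2, rose by 0.78 ± 0.16 (at CT22 0.35) and the peroxidase gene gpx1b (-0.74) was lower over the list alone. Insig1, a brake on sterol synthesis, passed over the list of 14 sterol and fatty acid genes alone (1.01 ± 0.26).

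No gene was called, over all genes or the list alone, among 23 photolyase and DNA repair genes (10 positive; ercc3, mre11a and neil1 with the smallest p), 26 heat shock genes (16 positive; serpinh1b, bag2 and cct2), 23 endoplasmic reticulum stress genes (12 positive; atf4a, dnajc3a and sel1l), 9 heme genes (3 positive; cpox, slc25a37 and alas2) and 24 cell cycle genes (10 positive; cdk2, dnmt1 and mcm3). Camera adjusted p was above 0.05 for all lists but the clock negative limb, skin and muscle.

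Markers of neighbouring tissues also differed between light and dark pools. All 8 kept skeletal muscle genes were higher in light (median 0.51 log2, camera adjusted p = 6.90e-04, adjusted p = 0.668 with an estimated correlation), with acta1a called and mb and ckma passing over the list alone; with spike-in class in the model the list was not called (camera adjusted p = 0.132). Of 19 skin and epithelium genes, 18 were positive (median 0.26, camera adjusted p = 6.90e-04, adjusted p = 0.942 with an estimated correlation); none was called and krt15, krt94 and icn passed over the list alone. The skin list was not called without CT18 (camera adjusted p = 0.164), and with spike-in class in the model it turned to the lower side (camera adjusted p = 0.330). Of 13 red blood cell genes, cahz fell (-0.79 ± 0.16, at CT22 -0.30) and klf1 was lower over the list alone. Gfap (0.61), of 10 glial genes, and mmp9 (0.81), of 16 leukocyte genes, passed over their lists alone. Neither 15 brain neuron genes (5 positive; nsg2, calb2b and gap43 with the smallest p), 3 habenula genes (kctd12.2, kctd12.1 and chrnb3a), 8 oligodendrocyte genes (olig2, sox10 and tspan2a), 13 connective tissue genes (col1a1a, postnb and col6a3) nor 5 endothelial genes (kdrl, aqp8a.1 and plvapb) held a call. With spike-in class in the model the oligodendrocyte list was higher in light (camera adjusted p = 0.0387, adjusted p = 0.821 with an estimated correlation), against an adjusted p of 0.890 on the lower side without it. In that model the dark array of CT22 alone parts class from light. Oligodendrocyte markers lay at -0.34 log2 on that array and at 0.64 on the light array of CT22, so a difference between these 2 pools cannot be told apart from light.

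With spike-in class in the model the light calls did not hold, and with spike-in level few did. With level beside the time-point block 8 probe sets were called, 6 of them among the 215: pfkfb4b (2.41 ± 0.34 log2, SE, limma), LOC567909 (2.25 ± 0.33), jun (1.90 ± 0.29), sik1 (-2.45 ± 0.37), the actin gene actb1 and a probe set without a gene symbol, the last 2 singled out after their values were seen. All 215 kept their direction there, with a median size of 0.71 log2 against 0.90, and per2 was at 1.93 ± 0.35 (adjusted p = 0.0923). With class beside the light and cosine terms 3 probe sets were called, all higher (med11, ulk1b and krit1, named after their values were seen), and none of the 215 light calls, of which 191 kept their direction (median 0.41 log2) with wider SEs (pfkfb4b 1.44 ± 0.46, jun 1.56 ± 0.29). With class and the time-point block the light term is the CT22 difference alone, and limma called 0 (550 at an unadjusted p under 0.05); within the 7 arrays of the higher class limma called 0, with 433 at an unadjusted p under 0.05, and the dark side then rested on 1 array. The 215 were called with the arrays used in all these fits, which favours agreement in direction. Of the 351 probe sets called without CT22, 65.0% went the called way there (median 0.26 log2). The share was 69.9% for the higher and 57.0% for the lower ones. Within the higher class per2 was at 1.35 ± 0.51, jun at 1.49 ± 0.27 and dusp1 at -1.91 ± 0.30 (SE, limma). Without the pair of CT22 the main model called 216 higher and 135 lower, and without that of CT10 58 and 13.

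Over the circadian cycle 4 of 10 clock negative limb genes, 3 of 8 clock positive limb and nuclear receptor genes and 3 PAR bZIP and nfil3 genes were called, some with opposite phases; per2 was not (0.52 ± 0.16, adjusted p = 0.218 by limma). The repressor genes bhlhe41 (amplitude 2.29 ± 0.17 log2, SE, peak at CT19.2), ciarta (2.34 ± 0.20, CT19.2), bhlhe40 (2.15 ± 0.30, CT22.2) and cry2 (0.90 ± 0.13, CT19.6) and the nuclear receptor gene nr1d2b (1.40 ± 0.18, CT20.0) peaked in the late subjective night. The activator genes rorcb (1.86 ± 0.17, CT5.4) and bmal1a (1.24 ± 0.19, CT6.9; not called without CT6 or CT10, adjusted p 0.0596 and 0.0590) and the bZIP repressor gene nfil3-5 (2.57 ± 0.25, CT7.3) peaked in the subjective day. These peak times come from 1 cycle sampled every 4 h, and some moved with the arrays used. From the dark and the light arrays alone, ciarta peaked at CT20.2 and CT18.2 and nfil3-5 at CT8.4 and CT6.6. The peak of nr1d2b stayed at CT20.1 and CT20.0. A shift of the peak between them was not tested by itself. The fitted peak of nfil3-5 was 35.5-fold and that of bhlhe41 24.1-fold above the trough. In all, 184 probe sets for 113 genes were called by the F-test in limma, with amplitudes of 0.40 to 2.57 (median 0.73), and of 20 named by the rule in the methods 12 lost their call when some time point was left out; 53 peaked between CT8 and CT12 and 41 between CT20 and CT24.

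The calls were more than expected among the clock negative limb (Fisher's exact test, adjusted p = 2.82e-04) and the clock positive limb and nuclear receptor genes (adjusted p = 0.00280); of the PAR bZIP and nfil3 genes, tefa peaked at CT20.0 and nfil3-6 at CT23.8. A further kept probe set of nr1d2b had an amplitude of only 0.14. Aanat2 had an amplitude of 1.05 ± 0.24 with a peak at CT14.2 and did not pass the threshold (adjusted p = 0.0681 by limma), but did without CT14 (amplitude 1.49, adjusted p = 0.00913). Tph1a, the only call among 19 melatonin and pineal genes, had an amplitude of 0.48 ± 0.10 with a peak at CT11.3 (adjusted p = 0.0424) and was not called when any 1 time point was left out (adjusted p 0.0659 to 0.375). Of 26 phototransduction genes 4 were called (adjusted p = 0.00797): pde6ha, gnb1b, pde6hb and rcvrn3, named after their values were seen. This list was not called with quantile normalization (adjusted p = 0.0818), with spike-in class in the model (adjusted p = 0.689) or from the dark arrays alone. The red cone opsin gene opn1lw1 (1.37 ± 0.18) peaked at CT7.3 and cyp27c1, which makes a longer-wavelength form of the visual chromophore, at CT20.9 (1.27 ± 0.19).

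**Figure D3:**
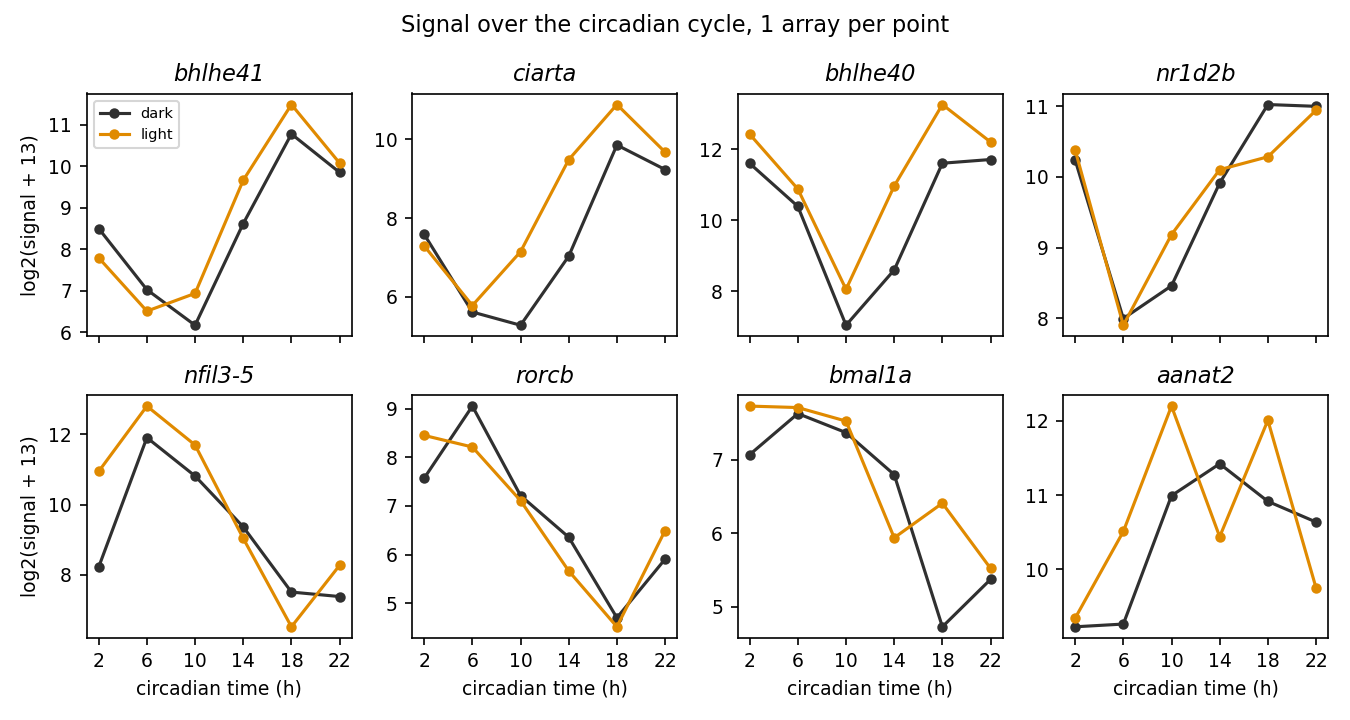
Log2 signal (with 13 added) against circadian time in hours for 8 genes, 1 point per array, dark in black and light in orange. Bhlhe41, ciarta, bhlhe40 and nr1d2b peak between CT19.2 and CT22.2 by the cosine fit, nfil3-5, rorcb and bmal1a between CT5.4 and CT7.3; aanat2 did not pass the threshold.

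A separate set of genes with high amplitude belonged to skin. Krt5 (1.66 ± 0.32, CT10.1), krt91 (1.52 ± 0.31, CT10.3) and cldni (1.54 ± 0.17, CT11.4), which encode keratins and a claudin of surface epithelium, were called, as were 3 other markers, cdh1, icn2 and krt18a.1 (the last with its peak at CT18.4), making 6 of 19 (Fisher's exact test, adjusted p = 2.12e-05); from the dark arrays alone the list was not called. Fgfbp2a (1.90 ± 0.23), si:dkey-183i3.5 (1.86 ± 0.22), the matrix protein gene postnb (1.37 ± 0.18) and si:ch211-76l23.4 (1.36 ± 0.26) peaked between CT9.9 and CT11.5 as well; without CT10 none of these 4, nor krt5 or krt91, was called (adjusted p 0.0518 to 0.299). The dark pool of CT18 was lowest of all arrays for skin markers (mean deviation -1.01 log2) and highest for brain neuron (0.94) and oligodendrocyte markers (1.05), while the light pool of CT18 was at 0.29, -0.26 and -0.13. No other list passed Fisher's test.

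**Figure D4:**
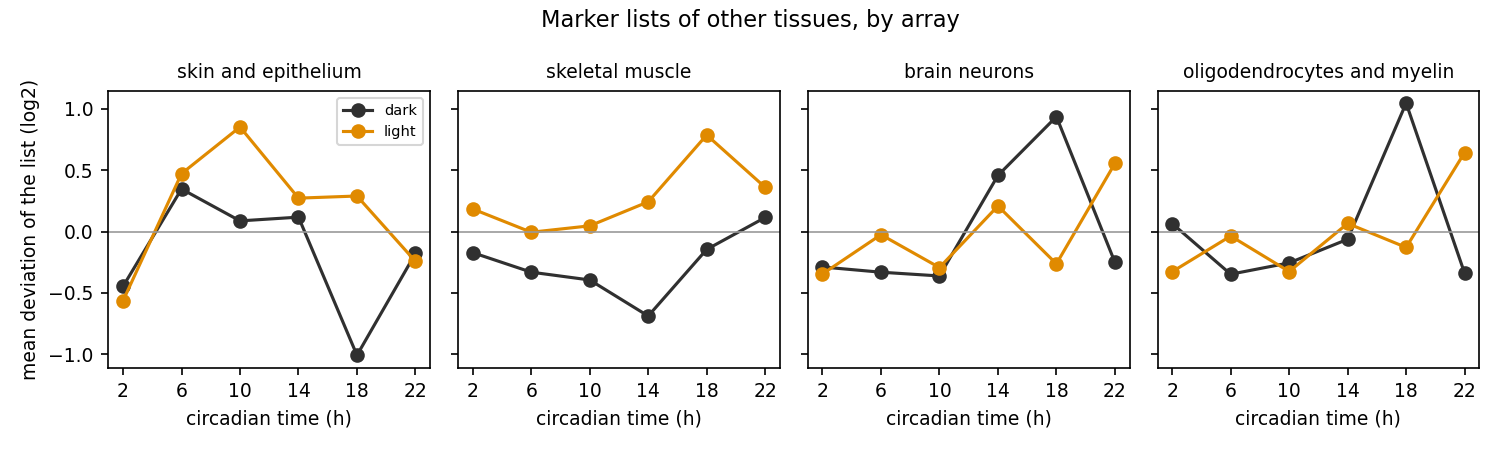
Mean deviation (log2) of the kept genes of 4 marker lists from their own means over the 12 arrays, against circadian time in hours, 1 point per array, dark in black and light in orange. The dark pool of CT18 lies at -1.01 for skin and at 1.05 for oligodendrocytes, and muscle markers are higher in the light pool at all 6 times.

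The time-of-day calls varied with the arrays used. With spike-in class in the model 134 probe sets were called, 118 of them among the 184; from the 6 light arrays alone, all of 1 class, 23 were called and 22 of these were among the 184. Leaving out CT10 left 48 calls, and leaving out CT18, the time of the pool with little skin signal, 113. Of the probe sets called for light, 13 were also called for time of day against 4.25 for independent lists, among them klf9 (peak at CT16.1), nfil3-6, bhlhe40 and zgc:193593; both tests used the same arrays.

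The size of the light response did not pass the test for variation over the cycle in any probe set. Limma called 0 of 9301 for the product of light with the cosine and sine (864 at an unadjusted p under 0.05, 465 by chance; smallest adjusted p 0.386), and 0 for subjective night against day (296 at an unadjusted p under 0.05). Per2 differed by 1.41, 1.50, 2.16, 0.66, 2.34 and 1.66 log2 from CT2 to CT22. Cry1a differed by 0.35, 0.77, 0.57, 0.67, -0.18 and 0.83. Jun ranged from 1.32 to 2.40, klf9 from 1.07 to 2.50, fkbp5 from 0.68 to 2.18 and egr2a from 0.32 to 1.54. Dusp1 ranged from -2.93 at CT6 to -0.81 at CT18, sik1 from -2.96 to -0.84 at the same times, and fosab from -2.71 at CT22 to -0.05 at CT18. In simulated data, changes of the light response of 1 log2 unit were mostly missed; sizes between 1 and 2 were not simulated.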

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

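The tests of skin tissue and of 4 single genes and the models with the spike-in class or level of the arrays were chosen after the controls or the calls had been seen; the test at CT22 and the counts over other splits were set before their results. In 116 sets of 6 values (22 of array measures, 94 of named genes), 8 held a value apart from the others by Dixon's ratio. Chance gives about 1 in 20, so the count itself is not far from chance. Of the 8, 5 were at CT22. Apart from atp5f1e, those at CT22 are measures of the same dark array and are not independent of each other.

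The first pattern is the standing of the dark array of CT22. It lay apart from the other 5 dark arrays in mean spike-in signal (10.59 log2 against 9.53 to 9.78), the cre control (19346 against 9378 to 10469), the highest signal (40396 against 23972 to 29791) and the middle GAPDH probe set (752 against 1174 to 1410). Of the 351 probe sets called from the other 5 time points, 65.0% went the called way at CT22 with a median of 0.26 log2. When each of the other times was left out in the same way, it was 93.0% to 98.6%, with medians of 0.74 to 1.17. At CT22 it was 69.9% of the 216 higher calls (median 0.30) and 57.0% of the 135 lower ones (median 0.09). At the other times left out it was 91.6% to 100% of the higher and 90.9% to 100% of the lower calls. The 65.0% lies between the even split that a pure hybridisation effect would give and the 75% set as the bound against it. The same test also took the size. The median at CT22 was 0.245 times that over the other 5 left-out times (0.26 against 1.06 log2). Most of the difference was thus absent where both arrays were of 1 class, which leans towards a class effect. It rests on 1 pair, so a class effect and a light effect cannot be told apart for the calls as a set. A weaker response in the late night, a biological alternative, stays open too. Of 32 splits of the arrays within times, 1, the real one, gave as many as 215 calls. The highest of the others gave 1. That share is under 0.05 but is the smallest that 32 splits can give, so chance is unlikely but not excluded. Exchanging the pair of CT22 alone follows the spike-in classes as closely as the real split and gave 0 calls. This pair thus leans with the others, as the 65.0% shows, but it is 1 pair. With spike-in level and the time-point block in the model 6 of the 215 calls stayed called. Pfkfb4b, LOC567909, jun and sik1 were picked from these, so that 4 of 4 stayed called was fixed by the choice. Their differences were at least as large there as without level, but this cannot exclude a straight-line effect of spike-in level for these 4 genes. A step between the classes cannot be told apart from light for them: 4 of 4 kept a light difference over 2 SE with class and cosine terms, and they differed by 1.73, 2.13, 1.58 and -2.39 at CT22, but the dark array of CT22 alone parts class from light, so a light effect stays a hypothesis.

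The second pattern is the peak of skin genes near CT10 among the time-of-day calls. Of the 13 skin markers that were not called for time, 13 were higher in light at CT18, with a median 1.02 log2 above that of all probe sets, so pools of the same circadian time differed in skin transcripts, which may reflect skin left on the dissected glands. Without CT18 krt5 and krt91 stayed called (limma F-test, adjusted p 0.00127 and 0.00363) with peaks at CT11.1, so the pools of CT18 alone did not make their peak. Both lost their call without CT2, CT6, CT10, CT14 or CT22. The levels of the called markers ran from 6.18 to 10.09 log2; the fluorescence used to find the gland would not remove attached skin. With spike-in class in the model 4 of the 6 called markers kept an adjusted p under 0.05, which does not settle whether class had a share. Of the markers, 5 of the 6 called and 7 of the 13 other markers peaked between CT7 and CT15, and a rhythm of skin genes themselves was not tested.

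The third pattern is the calls for time of day as a whole. The real order of the 6 time points gave 184 calls, and the highest of the other orders gave 77. Thus 1 of 60 orders gave as many, the smallest share that 60 orders can give. It is under 0.05, so chance is unlikely for the count but not excluded. For the light response by time, 2 of 60 orders, the real one included, gave as many as 864 probe sets at an unadjusted p under 0.05. That share is under 0.05, but another order gave 914 and no probe set was called with all arrays. Chance is therefore not excluded for a light response by time. Without CT22 there were 1 call and 1051, without CT6 543 and without CT14 507, against 465 expected by chance. For subjective day against night, 8 of 10 splits gave as many as 296, the highest other 1043 with CT2, CT6 and CT22 on 1 side; 10 splits are too few for a share under 0.05.

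Atp5f1e differed by -0.0876 log2 at CT22 against 0.67 to 1.12 at the other times. Chrnb3a differed by 0.79 at CT14 against -0.29 to 0.12, and its light difference was negative at all 3 subjective-day times and positive at all 3 night times (means -0.20 and 0.31, a difference of 0.51), which drew attention by its signs alone; its test of night against day did not pass (limma, adjusted p = 1.00). Of 94 named genes examined, chrnb3a was the 1 with opposite signs in day and night, a count that chance alone can give. Col1a1a differed by -4.10 at CT10 against -0.69 to 0.56, and mb by 1.195 at CT6 against 0.16 to 0.52.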

How the results depend on the processing

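Models with the spike-in classes or level were chosen after the data were seen; the other alternatives were set before. The 147 higher and 68 lower probe sets of light against dark went to 118 and 44 with no filter, 30 lower without the trend, 287 and 178 at a threshold of 0.1, 237 and 158 with array weights, 41 and 19 with 1 probe set per gene, and 0 and 0 with the exact sign-flip test, whose p-values from 6 pairs are too coarse for the adjustment. Without the time-point block (no replicate block) the counts were 97 and 30, or 164 and 96 with cosine terms. With spike-in class they were 3 and 0 (cosine terms) or 0 and 0 (block, which leaves the CT22 pair alone), with spike-in level 5 and 3 (6 of the 215), and in the higher class alone 0 and 0; the cause, class or the loss of dark arrays, was not tested. Leaving out 1 time point gave 58 to 216 higher and 13 to 135 lower; the highest were without CT22 and the lowest without CT10. Of 33 named genes called for light, 16 kept their call throughout and 17 lost it without some time point (adjusted p 0.0510 to 0.187): osbpl7, ackr3b, fosab, ggctb, gtf2f2a, hey1, slc25a20, tfdp1b, ccng2, bhlhe40, egr2a, keap1a, rpl35a, rpl31, psmd6, psme3ip1 and cahz.

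Time of day gave 122 calls without the trend, 339 at 0.1, 20 from dark arrays, 23 from light arrays, 67 with a 6-level factor and 48 to 121 leaving out 1 time point (12 of 20 named genes lost their call in some: krt5 and krt91 without CT10, adjusted p 0.249 and 0.293, and without 4 other times, si:ch211-76l23.4 without CT2, CT10 or CT14, up to 0.299, tefa without CT6, CT18 or CT22, up to 0.129, cry2 without CT10 or CT18, up to 0.0677, bmal1a without CT6 or CT10, up to 0.0596, bhlhe40, postnb, fgfbp2a and si:dkey-183i3.5 without CT10, 0.0932, 0.111, 0.0590 and 0.0518, cyp27c1 without CT22, 0.0557, and tph1a without any 1); fewer arrays or degrees of freedom enter most of these. Light by time and day against night each stayed at 0, except 1 call each without CT22 (range 0 to 1). Of the light lists, 3 were called, 0 with an estimated correlation, 0 by fry, 2 without the block and 3 to 5 leaving out 1 time point (without CT18 the skin list dropped out and the melatonin, antioxidant and ribosomal lists came in, all lower), and with class the clock negative limb and oligodendrocytes (0 with an estimated correlation); of the time-of-day lists, 4, 3 with quantile normalization or class (phototransduction lost) and 2 from dark arrays (skin lost too).

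Of the 37 named light genes that were called or of fixed name, none changed sign under the alternatives set before; of the 57 others, chrnb3a (-0.0891 without CT14, and with array weights), sox10 (0.0162 without CT2) and tspan2a (0.0806 without CT18) did, and 21 were called in at least 1, such as ercc3 with quantile or cyclic loess normalization, serpinh1b without CT18 and cdk2 without CT22. With class and cosine terms the sign turned for ggctb (0.39), hey1 (0.0455), slc25a20 (0.11), aanat2 (-0.58), exorh (-0.63) and the skin list (adjusted p 0.330, or 0.957 with an estimated correlation); with class and block, thus at CT22 alone, for aanat2 (-0.89), exorh (-0.84) and rpl35a (-0.0685); with spike-in level for cry5 (-0.22); in the higher class alone for ggctb (0.0285), hey1 (0.0686), slc25a20 (0.14), cry5 (-0.0358), aanat2 (-0.68) and exorh (-0.43); the cause was not tested.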

Other observations

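Both hypotheses in this part were formed after the light calls had been seen. Sik1, dusp1 and fosab, which were lower after light, are induced by cAMP in many cells, and light may lower cAMP in the pineal photoreceptors. A list of cAMP-responsive genes without those called or named kept 20 members, such as egr1, junba, nr4a1 and btg2; 11 of them were higher in light (median 0.04 log2, quartiles -0.19 and 0.25). Camera in limma gave the list a p of 0.570. The list neither bore the idea out nor excluded it, since its members went both ways.

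Fkbp5 and klf9, which were higher after light, are also induced by glucocorticoids, so a stress response to the light pulse could have raised them. Of 20 other glucocorticoid-responsive genes, among them tsc22d3, sgk1 and cebpd, 11 were higher in light (median 0.08 log2, quartiles -0.21 and 0.24). Camera in limma gave the list a p of 0.663, which left this hypothesis without support and not excluded.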
